A study of Mus musculus with 6 samples.

How the data were processed

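RNA of 6 Neuro2a samples was measured, 3 labelled as empty vector and 3 as RNA interference against USF1 and USF2. It was amplified and labelled with the Ambion WT Expression and Affymetrix WT Terminal Labeling kits and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, per the labels' protocols. The groups and replicate numbers were taken from the sample titles and the vector label. The authors deposited 1 table of 22891 transcript clusters by 6 arrays on a scale read here as log2. In it every cluster had a median of 0 over the 6 arrays (largest absolute median 5e-07), so the values are relative to the cluster's own median and no level is kept. The background correction, normalization between arrays and filter that made the table are not given in the sources used here. That the scale is log2 is not stated either and was taken from the rounding of the numbers. Differences between arrays were whole multiples (tolerance 0.05 of a step) of the single-precision step of numbers from 4 to 8 (4.77e-07) or from 8 to 16 (9.54e-07). This is the usual range of log2 array signals. The same step placed each cluster in a brightness class before centring, with 12893 clusters (56.3%) at 4 to 8, 9945 (43.4%) at 8 to 16, 0 below 4 and 53 unknown. A cluster whose arrays lie on both sides of 8, or a chance fit, can place a few clusters wrongly, and the class is not a measured level. The 6 columns were all different, and no other columns of samples were in the table.

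Gene names came from the platform annotation of the array. Of the clusters, 18087 had 1 gene symbol, 1145 had several and 3659 were unnamed. Names were compared through Entrez gene identifiers with a RefSeq gene table of assembly GRCm38.p6. In it 18023 clusters matched and 0 symbols changed. That table's coordinates are not given here because the deposited table names no genome build. Only clusters with 1 symbol were tested by name, which gave 16583 genes. Of these, 15722 had 1 cluster and 861 had several (at most 31), which were averaged. The design fixed before the data were examined named the cluster with the highest mean level instead, which centred values do not allow. Of the genes, 7543 were in the brighter class and 9040 were not.

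Changes are knockdown minus empty vector on the log2 scale, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend or robust variance, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 4 residual degrees of freedom and 3.79 prior degrees of freedom. A fold is 2 to the power of the change and may be compressed by the array. Counts and p-values called adjusted over the list alone use the same limma p-values with Benjamini-Hochberg adjustment within 1 gene list. They are not adjusted across the lists, so some lists can hold a call with no change at all. The 2 targets were also compared by an exact two-sided permutation test. Brightness classes and figures were made with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.

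The 33 gene lists were written from textbook knowledge before the data were examined. They include lysosomal hydrolases, lysosomal membrane proteins, the vacuolar ATPase, autophagy, regulators of lysosome number and mTORC1, the unfolded protein and integrated stress response, S phase, the respiratory chain, NRF2 antioxidant genes, catecholaminergic identity. They also include markers of glia, fibroblasts, macrophages and endothelium. Each list was tested with limma camera (preset correlation 0.01, two-sided, adjusted over the 33 lists), again with an estimated correlation, and with limma fry for a one-way change and for change in either direction. With an estimated correlation camera uses the 4 residual degrees of freedom, so with so few arrays it can hardly call a list. The 11 lists described were chosen after their values were seen. The named genes follow a rule fixed before the data were examined. It took the 2 targets, 6 other E-box factors and up to 4 members with the smallest p of each described list. It also took the genes past the threshold with the largest changes or, where under 5 passed in a direction, the 5 with the smallest p. Genes outside this rule are said to be so.

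The fit was tested on simulated data with the same 16583 genes, the spread of each array and 20 runs. With 200 changed genes per run it recovered 22.2% at a log2 change of 0.25, 84.9% at 0.5 and 98.9% at 1. With 12 changed genes it recovered 0%, 51.2% and 95% at these sizes. In each run the changed genes were spread evenly over these sizes, so the larger changes eased the adjusted threshold for the smaller ones. Runs with changes of 0.25 alone were not made. A one-way shift of 0.1 in a list of 25 genes was found by camera in 20 of 20 runs, a shift of 0.25 in both directions by fry in 20 of 20. Among 620 unchanged lists camera called 2 and fry 5. The simulated genes were drawn independently of each other, with variances drawn from the fitted prior and no difference between brightness classes. Members of the real lists had estimated correlations of up to 0.369. The simulated rates for lists therefore need not hold for the real lists. The alternatives tried were the replicate number as a block, fixed or random, quantile normalization, centring of arrays, array quality weights, all clusters, other thresholds, and leaving out each array in turn. Added after seeing the data were robust variance, brighter genes only, centring within brightness classes and genes with 1 cluster. The 4804 clusters with no symbol or several were tested apart from the named genes, in the fit of every cluster.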

Results

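Gene expression was measured in Neuro2a cells, a mouse neuroblastoma line used as a model of neuronal cells. The array, Affymetrix Mouse Gene 1.0 ST, used once for each of 6 samples, reads each gene with probes spread along its transcript. Of these, 3 arrays came from cells transfected with an empty vector and 3 from cells transfected with vectors for microRNA-based RNA interference against both Usf1 and Usf2. USF1 and USF2 are basic helix-loop-helix leucine zipper transcription factors that bind E-box sequences in promoters. The labels call the 3 arrays of a group biological replicates without saying whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical. The deposited table held 22891 transcript clusters, each given on a log2 scale relative to its own median over the 6 arrays. A gene can be compared between arrays but its level is not known. The number of arrays limits the precision: the median standard error of a change was 0.0561 on the log2 scale, and a typical gene needed a 1.09-fold difference to reach an unadjusted p of 0.05 in limma.

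The arrays were not equally spread. The standard deviation over all clusters lay between 0.0531 and 0.0780 on 5 arrays and was 0.159 on knockdown array 2. On that array the median of 229 olfactory receptor genes, which few cells outside the olfactory epithelium express, was 0.14. The median of the clusters in the dimmer class (4 to 8 on the log2 scale before centring) was 0.07, and that of the brighter class (8 to 16) was -0.03. On knockdown array 3 the olfactory receptor genes had a median of -0.07.

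**Figure D1:**
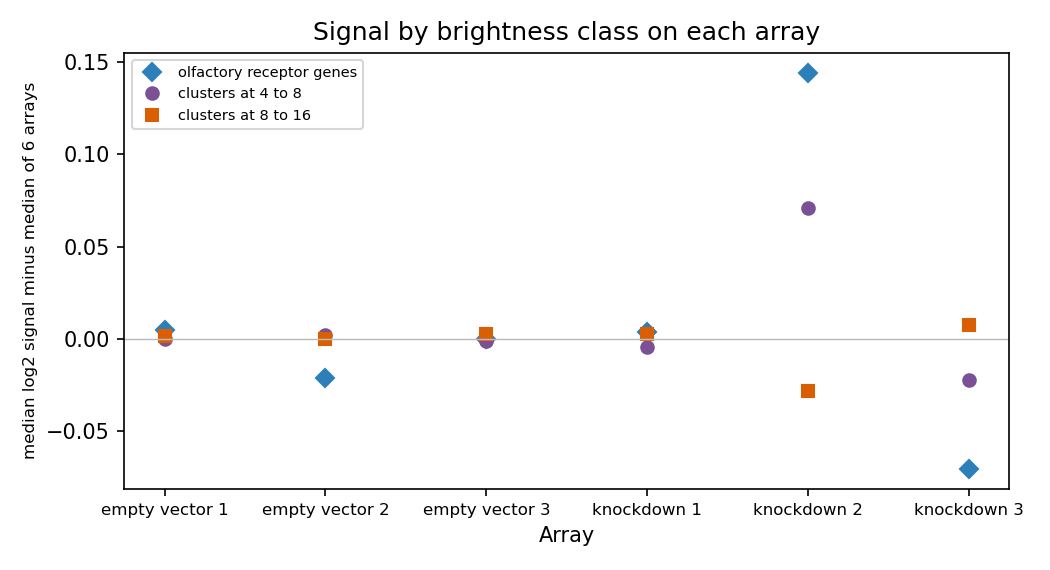
Median log2 signal relative to the median of the 6 arrays (vertical axis) on each array (horizontal axis), for 229 olfactory receptor genes and for the clusters in the dimmer (4 to 8) and brighter (8 to 16) class. Knockdown array 2 stands apart, with olfactory receptor genes at 0.14 and the brighter class at -0.03.

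The comparison of knockdown with empty vector asked which genes lie downstream of the USF factors. Lysosomal genes are the group named in the title of the series. Both targets were lower in the knockdown cells. Usf1 (cluster 10351616) had a mean relative log2 signal of 0.31 ± 0.12 (SD, n = 3) with empty vector and -0.24 ± 0.05 (SD, n = 3) with knockdown, a change of -0.55 ± 0.07 (SE) or 0.682-fold. Usf2 (cluster 10562172) had 0.22 ± 0.09 (SD, n = 3) and -0.16 ± 0.06 (SD, n = 3), a change of -0.38 ± 0.06 (SE) or 0.770-fold. All 3 knockdown arrays lay below all 3 empty vector arrays for each target. The exact two-sided permutation p was 0.10, the smallest that 3 against 3 arrays can give. In limma the adjusted p was 9.2e-05 for Usf1 and 2.0e-04 for Usf2 adjusted over the list alone, here the 2 targets, and 0.320 and 0.348 over all 16583 genes tested. Usf1 lay in the dimmer class and Usf2 in the brighter one. On these arrays the fall of both targets was partial. Protein was not measured, so how far USF activity fell is not known.

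Over all genes, 1 gene passed an adjusted p of 0.05 in limma. Dpp7 (cluster 10480699), a dipeptidyl peptidase of lysosomes and other vesicles, rose 1.63-fold (0.71 ± 0.05, SE, n = 3 arrays per group, limma adjusted p = 0.0148), with all 3 knockdown arrays above all 3 empty vector arrays. At an unadjusted p under 0.05 limma counted 705 genes, 266 higher and 439 lower. This is 4.25% of the genes where 5% would be reached with no change at all. After Dpp7, the genes with the smallest p among those higher after knockdown were Sgsm1 (1.30-fold), the aspartic protease Ctsd (1.21-fold), the heme-degrading enzyme Hmox1 (1.25-fold) and Vps50, a subunit of an endosomal recycling complex (1.24-fold). Among those lower, after Usf1, they were Tmc8 (0.797-fold), the lysosomal cystine exporter Ctns (0.727-fold), the vitamin B12 carrier Tcn2 (0.816-fold) and the secreted galectin-binding protein Lgals3bp (0.753-fold). None of these 8 genes passed the threshold over all genes, with limma adjusted p between 0.320 and 0.533. For each the 3 knockdown arrays lay on 1 side of the 3 empty vector arrays, which chance gives for 10% of genes not picked by p. These 8 were picked by p in the same arrays, so the separation adds no support. Other E-box factors had small changes with limma adjusted p above 0.99. They were the lysosomal regulators Tfeb (0.06 ± 0.04, SE), Tfe3 (-0.01 ± 0.05) and Mitf (-0.04 ± 0.07), and Myc (0.03 ± 0.04), Mycn (-0.06 ± 0.05) and their partner Max (0.08 ± 0.04). Tfeb and Mitf lay in the dimmer class, so whether the arrays could read a change in them is not known. The signs of Tfe3 and Mitf turned under other settings. Tfeb was at 0.03 without empty vector array 2, Myc at 0.0077 and 0.04 without knockdown arrays 1 and 2, and Mycn at -0.10 and -0.03 without empty vector arrays 1 and 2. The single call was lost without empty vector array 1, 2 or 3 (limma adjusted p for Dpp7 of 0.326, 0.222 and 0.264; 779, 433 and 369 genes at an unadjusted p under 0.05) or without knockdown array 1 (0.0821; 569 genes). It held without knockdown array 2 or 3, where 1248 (417 higher, 831 lower) and 1228 genes (614 higher, 614 lower) were at an unadjusted p under 0.05. Over 16 alternatives, these fits among them, the change of Dpp7 lay between 0.66 and 0.78. Its size therefore moved little where the call was lost. With array quality weights 1111 genes passed, with weights of 33, 0.136 and 0.441 on knockdown arrays 1, 2 and 3. The knockdown mean in that fit was in effect that of 1 array, so this count is no support for an effect of the knockdown.

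**Figure D2:**
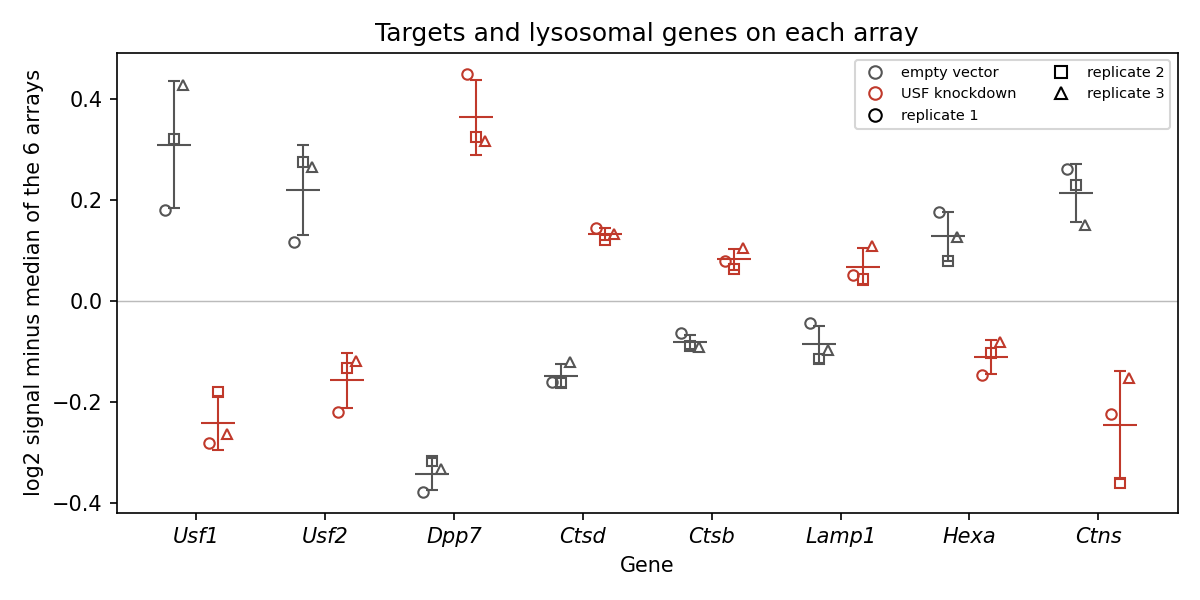
Log2 signal relative to the median of the 6 arrays (vertical axis) for the 2 targets and 6 lysosomal genes (horizontal axis), 1 marker per array, with the mean and SD of each group as bars (n = 3). The groups do not overlap for any of the 8 genes, with Usf1, Usf2, Hexa and Ctns lower and Dpp7, Ctsd, Ctsb and Lamp1 higher after knockdown. The 6 lysosomal genes were among those with the smallest p of their lists, which favours such a separation. Lamp1 did not pass within its list (limma adjusted p = 0.113 over the list alone).

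Lysosomal hydrolases, the enzymes that break down proteins, glycans and lipids in the lysosome, changed in both directions within their list. Of the 47 measured of 54 listed, 4 rose, 4 fell and 39 did not pass in limma adjusted over the list alone, with 4 higher and 7 lower at an unadjusted p under 0.05. The list also holds proteins that are not hydrolases themselves, among them Psap, Gm2a, Hgsnat and, of the 4 that fell, Sumf1. Over all genes 1 passed. Those that rose were Dpp7, Ctsd (0.28 ± 0.04, SE, limma adjusted p = 0.0028 over the list alone), the cysteine protease Ctsb (0.16 ± 0.04, 0.0388) and the tripeptidyl peptidase Tpp1 (0.21 ± 0.06, 0.0388). Those that fell were Hexa, a subunit of the hexosaminidase that degrades a ganglioside (-0.24 ± 0.05, SE, limma adjusted p = 0.0131 over the list alone), Idua and Naglu, which degrade glycosaminoglycans (-0.17 ± 0.04 and -0.19 ± 0.05, each 0.0388), and Sumf1, an enzyme of the endoplasmic reticulum that activates sulfatases (-0.18 ± 0.05, 0.0388). Tpp1, Idua, Naglu and Sumf1 are named after their values were seen, to complete the count. Idua lay in the dimmer class. A one-way shift of the list did not pass (median 7.4e-05, limma camera adjusted p = 0.969). The limma fry test found change in either direction (adjusted p = 1.14e-04), a test chosen after seeing the data that does not compare the list with other genes. It can rest on 1 member with a large change, and for no list was it rerun without the leading member. Leaving out 1 array at a time, the calls for Dpp7 and Ctsd held each time and that for Hexa in 3 of 6 fits, lost without empty vector array 1 or 3 or knockdown array 1. The calls for Ctsb, Tpp1, Idua and Naglu held in 1 of the 6 fits, without knockdown array 2, and that for Sumf1 in 0, with limma adjusted p over the list alone of up to 0.182.

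Of the lysosomal membrane proteins, 41 measured of 43 listed, 1 passed in limma adjusted over the list alone, against 0 over all genes. Npc2, in this list, is a soluble protein. Ctns fell to 0.727-fold (-0.46 ± 0.06, SE, limma adjusted p = 0.0039 over the list alone) and passed in each fit without 1 array. It lay in the dimmer class. Mfsd1, a lysosomal transporter, had a change of 0.20 ± 0.05 (SE, limma adjusted p = 0.0554 over the list alone), Lamp1, a major glycoprotein of the lysosomal membrane, 0.15 ± 0.04 (0.113), and Litaf -0.13 ± 0.06 (0.374). A one-way shift of the list did not pass (limma camera adjusted p = 0.841, upward, with a median of -0.0040 and a mean of -0.0033 of the opposite sign). Change in either direction was found by limma fry (adjusted p = 0.00177), but not without knockdown array 1 (0.0656). Over both lysosomal lists, 9 genes were called within their lists, 4 higher and 5 lower. Adjusting the 88 genes of both lists together, the first way tried, gave 5 calls, 3 higher and 2 lower. The count per list was chosen after seeing this. That count of 9 became 3 without empty vector array 1, 3 without empty vector array 3 and 3 without knockdown array 1, 4 without empty vector array 2, 5 without knockdown array 3 and 8 without knockdown array 2.

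**Figure D3:**
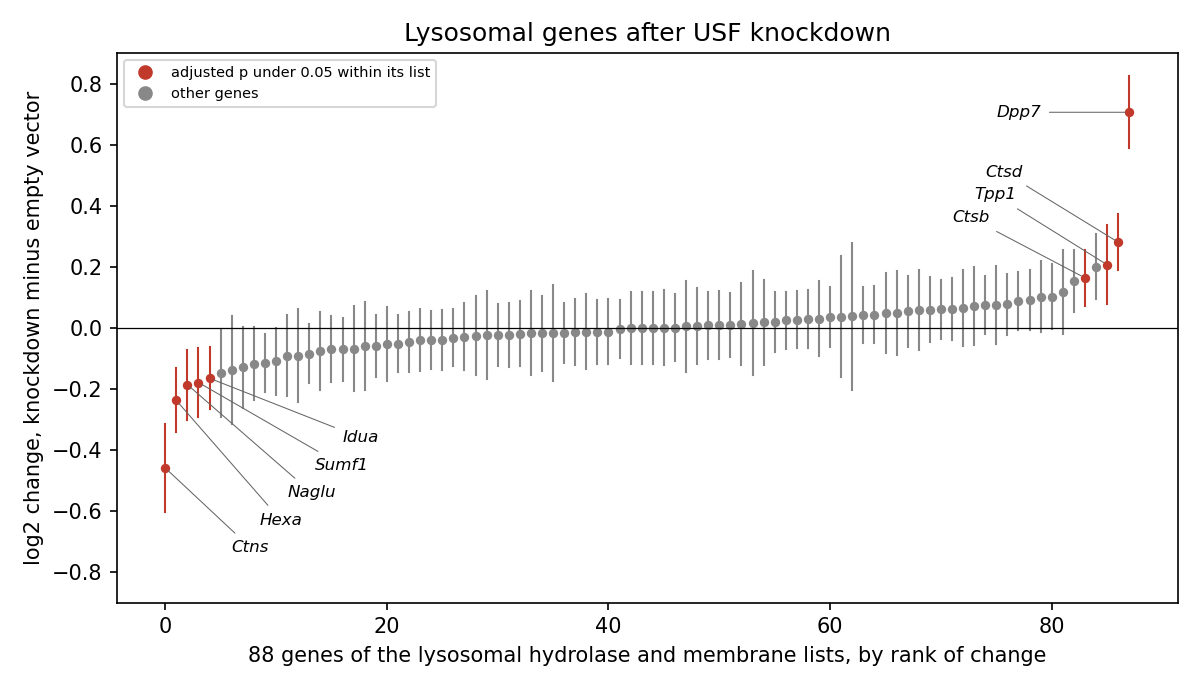
Log2 change after knockdown (vertical axis) of the 88 measured genes of the 2 lysosomal lists, ordered by change (horizontal axis), with 95% confidence intervals from limma over 3 arrays per group as lines. The 9 named genes passed within their list, 4 of them higher, up to 0.71 for Dpp7, and 5 lower, down to -0.46 for Ctns.

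Subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, had small changes with a median above 0. Of 17 measured of 18 listed, 0 passed in limma over the list alone or over all genes, with 3 higher and 1 lower at an unadjusted p under 0.05. These were Atp6v1a (0.14 ± 0.04, SE), Atp6v1b2 (0.13 ± 0.04), Atp6v0b (0.12 ± 0.04) and Atp6v1d (-0.17 ± 0.07). The median was 0.03 and the limma camera adjusted p was 0.0553 (adjusted p = 0.467 with an estimated correlation of -0.038, which is below the preset 0.01). Without empty vector arrays 1, 2 and 3 it was 0.230, 0.0329 and 0.0570, and without knockdown arrays 1, 2 and 3 it was 0.206, 0.0405 and 0.180. Change in either direction was found by limma fry (adjusted p = 0.00177). Of the autophagy genes, 44 measured of 45 listed, 0 passed in limma over the list alone or over all genes, with 2 higher and 2 lower at an unadjusted p under 0.05. Atg10, an enzyme that joins ATG12 to ATG5, had a change of -0.16 ± 0.04 (SE), the autophagosome proteins Map1lc3b and Map1lc3a 0.16 ± 0.05 and 0.15 ± 0.05, and the mitophagy receptor Bnip3 -0.21 ± 0.07, which was -0.14 without knockdown array 2. The autophagy list had a median of -0.0069 with a limma camera adjusted p of 0.957 in the upward direction. Without knockdown array 2 its median was 0.03 (limma camera adjusted p = 0.0470).

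Among regulators of lysosome number and mTORC1 signalling, 25 measured of 27 listed, 1 fell in limma adjusted over the list alone, against 0 over all genes. This was Rragb, a GTPase that recruits mTORC1 to lysosomes when amino acids are present, at 0.710-fold (-0.49 ± 0.10, SE, limma adjusted p = 0.0389 over the list alone). Its call held in 2 of 6 fits without 1 array (limma adjusted p over the list alone of 0.00224 to 0.265, lost without any of the empty vector arrays or knockdown array 1). The call of Rragb was not adjusted across the lists tested, so it can have arisen by chance. Lamtor1 and Lamtor2, parts of the lysosomal anchor of the same GTPases, had changes of 0.18 ± 0.05 and -0.13 ± 0.05 (SE), and Flcn, which acts on these GTPases, 0.13 ± 0.05. The list had a median of -0.0098 (limma camera adjusted p = 0.996) and a limma fry adjusted p of 0.0261 for change in either direction. The fry call was lost without empty vector array 1 (0.0775) or 3 (0.184) and without knockdown array 1 (0.471) or 3 (0.0557).

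Beyond the hydrolase, membrane protein, vacuolar ATPase and autophagy lists, 29 others were tested and 4 of them moved one way in limma camera with its preset correlation. Genes of the unfolded protein and integrated stress response rose as a list (28 of 28 measured, median 0.02, limma camera adjusted p = 0.00355, and 0.440 with an estimated correlation). That estimate was 0.0023, below the preset 0.01, so correlation between members does not account for the higher p. With an estimated correlation camera uses the 4 residual degrees of freedom, which raises p. Over all 33 lists the lowest adjusted p in that form was 0.440, so its lack of calls decides little. In the stress response list 0 genes passed in limma over the list alone and 7 were at an unadjusted p under 0.05, all higher. Among them were the transcription factor Ddit3 (0.27 ± 0.06, SE), Sesn2 (0.18 ± 0.05), Herpud1 (0.15 ± 0.04) and the pseudokinase Trib3 (0.15 ± 0.05). Its medians were 0.04, 0.03 and 0.04 on knockdown arrays 1, 2 and 3 against the mean of the empty vector arrays. Its call was lost without knockdown array 3 (limma camera adjusted p = 0.110), and its median was 0.04 without knockdown array 2. Genes of S phase and DNA replication fell as a list (24 of 25 measured, median -0.04, limma camera adjusted p = 0.0493, and 0.467 with an estimated correlation). Here too the estimate, -4.4e-04, lay below the preset one. Members with the smallest p were Gins1 (-0.19 ± 0.06, SE), Tyms (-0.11 ± 0.05), Rrm2 (-0.11 ± 0.05) and E2f1 (-0.10 ± 0.05), with Rrm2 at -0.07 without empty vector array 2 and E2f1 at -0.06 without knockdown array 1. Subunits of the mitochondrial respiratory chain fell as a list (29 of 34 measured, median -0.03, limma camera adjusted p = 0.0493; adjusted p = 0.769 with an estimated correlation). Its leading members were Uqcrfs1 (-0.12 ± 0.04, SE), Ndufa2 (-0.12 ± 0.05), Ndufa1 (-0.18 ± 0.10) and Sdhb (-0.07 ± 0.04). Ndufa1 was at -0.08 without knockdown array 2 and -0.12 without empty vector array 3. Markers of Schwann cells and other glia rose as a list (11 of 14 measured, 2 of them in the brighter class, median 0.05, limma camera adjusted p = 0.0493; adjusted p = 0.769 with an estimated correlation). The members with the smallest p were Aqp4 (0.09 ± 0.05, SE), Erbb3 (0.08 ± 0.05), Olig1 (0.09 ± 0.06) and Gfap (0.12 ± 0.08). Without knockdown array 2 Aqp4, Olig1 and Gfap were at 0.05, 0.06 and 0.05, and Gfap was at 0.18 without empty vector array 2. In these last 3 lists 0 genes passed in limma over the list alone, with 2, 1 and 0 at an unadjusted p under 0.05.

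On knockdown array 2, the one with the wide spread, the S phase, respiratory chain and glial lists had medians of -0.08, -0.06 and 0.13 against the empty vector mean. These medians were -0.04, -0.0082 and 0.02 on knockdown array 1 and -0.04, -0.03 and 0.02 on knockdown array 3. Without knockdown array 2 their limma camera adjusted p were 0.391, 0.805 and 0.560, at medians of -0.0381, -0.0056 and 0.0144. Without empty vector array 1, 3 or knockdown array 3 none of these 3 passed either (limma camera adjusted p of 0.0502 to 0.192), and the respiratory chain list was also lost without empty vector array 2 (0.141, at a median of -0.02). The S phase median was -0.0188 without empty vector array 3, and the glial one 0.03 without empty vector array 1 and 0.08 without knockdown array 3. The markers of other cell types that a culture could hold did not pass in limma camera: fibroblast and mesenchymal (median 0.02, adjusted p = 0.739), macrophage and blood cell (0.05, 0.120), and endothelial and epithelial (0.05, 0.303). The last 2 medians were about as large as that of the glial list, and on knockdown array 2 the 3 lists were at 0.13, 0.09 and 0.09 against the empty vector mean. On knockdown array 1 they were at -0.02, 0.07 and 0.0048. On knockdown array 3 all 3 lay below 0, at -0.09, -0.02 and -0.03. Quantile normalization and centring the arrays on their medians each left 1 of the 4 lists, the stress response list. With centring the S phase, respiratory chain and glial medians stayed at -0.04, -0.03 and 0.05 and each limma camera adjusted p was 0.0503. With quantile normalization the medians were -0.04, -0.02 and 0.04 (limma camera adjusted p of 0.125, 0.252 and 0.167).

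In each of 2 further lists 1 gene passed in limma adjusted over the list alone. That adjustment does not extend across the lists tested. With no change at all, some lists can therefore hold such a call by chance. Among NRF2 antioxidant genes, 15 measured of 16 listed, Hmox1 rose 1.25-fold (0.32 ± 0.05, SE, limma adjusted p = 0.00325 over the list alone) and held in each fit without 1 array. Cat (0.09 ± 0.04), Nqo1 (-0.11 ± 0.06) and Gclm (0.09 ± 0.05) did not pass. Nqo1 was at -0.07 without empty vector array 2 or knockdown array 2, and Gclm at 0.05 without knockdown array 3. Among genes of catecholaminergic and sympathetic identity, 15 measured of 19 listed, Dbh, which converts dopamine to noradrenaline, fell to 0.842-fold (-0.25 ± 0.05, SE, limma adjusted p = 0.0212 over the list alone). Dbh lay in the dimmer class. It passed in 2 of 6 fits without 1 array, and its limma adjusted p over the list alone was up to 0.120 without an empty vector array or knockdown array 1. The nicotinic receptor subunits Chrna3 (-0.13 ± 0.04, SE) and Chrnb4 (0.17 ± 0.06) and the decarboxylase Ddc (-0.10 ± 0.06; -0.06 without knockdown array 3) did not pass. Over all genes 0 members of these 2 lists passed in limma. For change in either direction limma fry gave an adjusted p of 0.0117 for the NRF2 list, which passed in 1 of 6 fits without 1 array (0.00492 without knockdown array 1). It was 0.0775, 0.180 and 0.104 without empty vector arrays 1, 2 and 3, and 0.0704 and 0.0745 without knockdown arrays 2 and 3. For the catecholaminergic list it was 0.00177, with 0.0725 without empty vector array 1 and 0.205 without knockdown array 1. In the NRF2 list Hmox1 was the only member at an unadjusted p under 0.05 in limma. The fry value of that list can therefore rest on Hmox1 and does not show change of the list as a whole. The 22 lists not described here held 0 genes past the threshold within their list.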

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

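Robust variance, brighter genes only, centring within brightness classes, genes with 1 cluster, the count of lysosomal genes called within their lists and the limma fry tests in either direction were chosen after seeing the data. The other alternatives were fixed before. Not run were the filters on dim clusters, variance trends and the floor, since centred values hold no level, and list tests for the random replicate block or for every cluster. Averaging the clusters of a gene became the fit reported. Over 15 and 16 alternatives Usf1 stayed between -0.62 and -0.49 and Usf2 between -0.46 and -0.35, and of 1004 values of the 64 other named genes 998 kept their direction. All of these genes but the fixed E-box factors were picked by p or by their values in the same arrays. That they kept their direction is therefore little support. Too little is known of signal over background to say which dim genes the arrays could read. Unless said otherwise, the cause of a change was not tested.

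The replicate numbers were not shown to pair the arrays. Deviations of arrays with the same number from their group means correlated at 0.003, 0.082 and 0.036, and array 1 with empty vector correlated better with another number (0.053). With the replicate number as a block, limma called 0 genes (636 at an unadjusted p under 0.05; limma adjusted p for Dpp7 0.193), 3 lysosomal genes within their lists instead of 9, and fry in either direction gave 0.109 for the membrane, the vacuolar ATPase and the mTORC1 regulator list. The respiratory chain list was lost in limma camera (0.0878), which left 3 of the 4 other lists. As a random block its correlation was 0.044.

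The count of genes was 0 at an adjusted p under 0.01, and between 0 and 1 leaving out 1 array at a time. With array quality weights it was 1111, 412 higher and 699 lower, with weights of 33 on knockdown array 1 and 0.136 on knockdown array 2, from a fit that gave 1 convergence warning. With these weights limma gave Usf1 -0.62 (adjusted p = 3.45e-04), Usf2 -0.46 (6.35e-04) and 27 lysosomal genes within their lists. In the 9 other splits of the arrays, weights gave 0 genes and a weight of at most 4.65. The weighted fit of the real split rests in effect on 1 knockdown array, so its counts do not compare with those of the other splits. Leaving out 1 array, the limma adjusted p over all genes lay between 0.0978 and 0.9997 for Usf1 and between 0.137 and 0.9997 for Usf2.

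The lists with a median near 0 changed sign. The hydrolases were at -5.8e-04 in brighter genes only and between -0.0168 and 0.0146 leaving out 1 array. The membrane proteins were at 0.0059 after quantile normalization, 0.0262 with weights, 0.0036 with centring within classes and -0.0140 to 0.0112 leaving out 1 array, where fry in either direction ran from 0.00499 to 0.0656. Autophagy was at 0.0133 after quantile normalization, 0.0275 with weights, 6.8e-04 with centring within classes and -0.0208 to 0.0258 leaving out 1 array. The vacuolar ATPase list passed in brighter genes only (0.0441, limma camera adjusted p = 0.00494) and with centring within classes (0.0412, 0.0344). It lay between 0.0276 and 0.050 leaving out 1 array, and its camera adjusted p ran from 0.00494 to 0.467 over all alternatives. Tfe3 was at 0.0136 after quantile normalization, 0.0019 with centring within classes and -0.0391 to 0.0327 leaving out 1 array, and Mitf at -0.104 to 0.0102. The count of 4 other lists became 1 with quantile normalization, centring of arrays, weights, brighter genes only, centring within classes or genes with 1 cluster, 0 with an estimated correlation, 0 with fry, and 1 to 7 leaving out 1 array. The form with an estimated correlation rests on 4 residual degrees of freedom and could hardly call a list, so its 0 decides little. In either direction by fry, the mTORC1 regulator list was also lost among genes with 1 cluster (0.0978) and the catecholaminergic list in brighter genes only (0.216). The 9 lysosomal genes became 3 to 8 leaving out 1 array.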

Other observations

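The tests of other splits for the lysosomal genes and for the gene count, the test of a mislabelled array, the test of dim genes, the tests of compression for the S phase, respiratory chain and glial lists one by one, the Fisher test across genes and the fry tests in either direction were chosen after the result was seen. Outside the fixed lists, and named after their values were seen, 5 genes are given here that had small p in limma without passing over all genes. Fuca2, a fucosidase, was at 0.762-fold (-0.39 ± 0.07, SE, limma adjusted p = 0.559) and Renbp, an epimerase of amino sugars, at 0.774-fold (-0.37 ± 0.08, 0.717). Washc2 and Washc5, subunits of the WASH complex that forms actin on endosomes, were at 1.16-fold (0.22 ± 0.04, SE, limma adjusted p = 0.616) and 1.14-fold (0.19 ± 0.04, 0.899), and Smcr8, part of a complex that acts on autophagy, at 1.16-fold (0.22 ± 0.05, 0.759). For each of these 5 genes the knockdown arrays lay on 1 side of the empty vector arrays. They were picked for a small p in the same arrays, so this adds no support. A hypothesis that the whole WASH complex went up was tested on the other members, Washc1 (0.06 ± 0.05, SE), Washc3 (-0.05 ± 0.05) and Washc4 (0.0084 ± 0.06). Their mean change of 0.0051 lay below the bound set for it beforehand, which argues against a rise of the whole complex.

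Among the 88 genes of the 2 lysosomal lists, 11 had an unadjusted limma p under 0.01, 6 higher and 5 lower, against 0.801 expected from the 151 such genes among all (Fisher's exact test across genes, which are not independent replicates, p = 4.34e-10). The count was 8, 4 and 5 without empty vector arrays 1, 2 and 3, and 5 and 6 without knockdown arrays 1 and 3. It was 6 with the replicate number as a block, and 10 without knockdown array 2, which argues against the compressed array as the cause. Among all genes, those at this p numbered 128, 72 and 60 without empty vector arrays 1, 2 and 3. They numbered 83 and 199 without knockdown arrays 1 and 3, and 119 with the block. Without knockdown array 2 they numbered 314 against the 151 with all arrays, so relative to all genes the lysosomal excess was smaller there. In a limma fit of brighter genes only, 9 of 71 lysosomal genes were at this p against 1.53 expected (one-sided Fisher's exact test across genes, p = 1.95e-05), which argues against noise of dim genes as the whole cause; the share of the 11 in the brighter class, 81.8%, decides nothing beside the 80.7% of all 88. Of the 10 splits of the 6 arrays, 1, the real one, gave 9 calls within the lists and the highest other gave 0, but 10 splits are too few for a share under 0.05. An effect of the partial fall of Usf1 and Usf2 RNA on single lysosomal genes stays open as a hypothesis, as do off-target effects of the vectors, which were not tested.

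A hypothesis was that brighter members of the lysosomal lists went up and dimmer ones down. At an unadjusted limma p under 0.05, 0 of 6 higher and 3 of 8 lower genes lay in the dimmer class (Fisher's exact test across genes, p = 0.209). The bound set beforehand for excluding it, a p of 0.05 or more, was wrong, since 0.209 was the smallest p these numbers allow in that direction, so the hypothesis cannot be told apart from no relation.

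Knockdown array 2 had a standard deviation over clusters of 0.159, against 0.0531 to 0.0780 on the others. A compressed signal range, with dim clusters too high and bright ones too low, is a candidate explanation: the olfactory receptor median on that array lay 0.139 above the highest of the other 5 arrays, and the brighter class was lowest there. A control array under a knockdown label is argued against by Usf1 and Usf2, which both lay below the lowest control array, by at least 0.25 against control standard deviations of 0.125 and 0.0888. Whether amount or quality of RNA, hybridisation or the cells themselves set this array apart was not tested. The split that put empty vector array 1 with knockdown arrays 1 and 3 gave 1483 genes at an unadjusted limma p under 0.05 and 0 past the adjusted threshold, more at the unadjusted p than the 705 of the real split, which points to a structure of the arrays besides the knockdown.

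One-way shifts of gene lists were 4 in the real split, in limma camera with its preset correlation. In all, 3 of the 10 splits gave at least as many, with 5 as the highest other, and 10 splits are too few for a share under 0.05. The stress response list passed without knockdown array 2 (camera adjusted p = 2.32e-04), which argues against compression of that array as its cause, and transfection or RNA interference stress as such was not tested. Of the other 3 lists, 1, the glial one, had the far smaller shift on knockdown arrays 1 and 3 that compression of array 2 would give (smaller ratio to array 2 of 0.162), so compression is a candidate explanation there. Compression and knockdown cannot be told apart for the respiratory chain list (smaller ratio 0.147, on array 1, with more of the shift kept on array 3) or the S phase list, which kept its median without array 2 (-0.0381 against -0.0415 with it; smaller ratio 0.522) but not without empty vector array 3 (-0.0188), and passed in neither fit.

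For the 4 lysosomal and autophagy lists, the number of the 10 splits with a camera p as small as the real one was 10 for the hydrolases, 7 for the membrane proteins, 1 for the vacuolar ATPase and 10 for autophagy. The real p were 0.929, 0.670, 0.00838 and 0.870 in limma camera before adjustment, and the smallest of the other splits 0.0247, 0.0502, 0.0362 and 2.66e-04, again with too few splits for a share under 0.05. The count of 1 gene past the limma threshold over all genes was reached by 1 of the 10 splits, the real one, and the highest other gave 0.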
